A study of Mus musculus with 6 samples.

How the data were processed

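Total RNA of NIH3T3 cells, an established line of mouse embryonic fibroblasts, was measured on 6 single-colour (Cy3) Agilent gene expression arrays. Cells stably infected with a retroviral vector for GGCT (gamma-glutamylcyclotransferase) were on 3 arrays and cells with the control vector on the other 3. Per the labels, 3 independent experiments were performed. The labels do not give the species of the GGCT sequence in the vector, and do not say whether each experiment used separately infected cells. Groups and replicate numbers were taken from the sample titles.

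Per the file headers, the scanner files hold background-subtracted and spatially detrended spot intensity, made with Agilent Feature Extraction 12.1.0.3 (protocol GE1_1200_Jun14) and not scaled between arrays. They also hold flags for spots that are well above background, saturated or outliers. The values that the authors deposited as processed data are on a log2 scale. Checked against the scanner files, they are log2 intensities shifted per array by its 75th percentile and then centred per probe on the median of the 3 control arrays. That median lay within 1e-06 of 0 in 100% of 56743 probes, and 99.9% of the differences between arrays lay within 0.01 of those of the scanner values. The deposited values were used only as an alternative.

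In the values reported here, the log2 processed signal of each spot had the 75th percentile of its array (non-control spots) subtracted. Spots with an outlier flag were set to missing, control spots were left out and spots of one probe were averaged. A probe was kept when it was well above background on at least 3 of the 6 arrays, whatever the group, and a gene was represented by its kept probe of the highest mean signal. The scanner files give no gene symbol column. Probes were named by matching the RefSeq transcript accession in the files to the mouse reference annotation (GRCm38.p6), and a probe without a match was tested under its accession. The file headers name build mm9, and no coordinates are given here. Of 56605 probes, 34566 matched a symbol and 32419 passed the filter. They stood for 24935 genes or accessions, 14527 with a symbol and 10408 by accession only.

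The arrays came from different versions of the array design, and 522 probes had another accession in the earlier version. The later version was used. Among the genes named here this applies to Cthrc1 (Alox5 in the earlier version), Ccn4 (Sik1) and Oplah (Cartpt), so the identity of these probes is open.

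Genes were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the packages data.table (1.17.8) and jsonlite (2.0.0) for reading and Python 3.11.15 with matplotlib 3.10.9 for plots. Differences are GGCT minus control on the log2 scale with their SE, n = 3 per group. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over all genes tested, two-sided. The number of arrays limits the precision, and the median SE was 0.13. The p-values measure the spread between these samples. As the labels do not say how many infections were done, this may be the spread between cultures of 1 infected population per vector. The p-values would then not measure how infections differ. Where no array of a group was well above background for a gene, the fold is a lower bound. It was computed against the lowest signal called well above background, averaged over those arrays, and is written "at least". Where 1 or 2 arrays of a group were not well above background, their values were raised to that signal in the same way. Fitted folds of such genes are not given, except for Rnf207, whose values all lay above that signal, so that none was raised and its fold is no lower bound.

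Gene lists were tested with limma's camera (preset correlation between genes of 0.01), adjusted over 37 lists, of which 31 are pathways and gene families and 6 are markers of other cell types. A list needed at least 5 measured genes. The lists, the rule for named genes and the alternatives of the first group below were fixed before the data were examined. The rule names Ggct, the 12 genes highest and the 12 lowest by log2 difference among those past the threshold with separated groups and a gene symbol, and up to 4 members of each list with the smallest adjusted p past the threshold. Other genes are said to be chosen after their values were seen. Not every gene that the rule names is reported here. Camera was repeated with the correlation estimated from the data for each list. Of the 17 lists past the threshold, 0 passed with an estimated correlation (smallest adjusted p = 0.245), while fry, which tests whether a list's genes move one way on balance without comparing them with other genes, passed 24 of the 37.

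Replicate 1 of both groups was hybridised on one slide and scanned together, and replicates 2 and 3 of both groups were on another slide with its own scan. Slide and scan therefore split the arrays the same way, and both groups were on each. Whether the replicate numbers pair the samples was checked from deviations from the group mean across genes. Control and GGCT arrays of the same number had correlations of 0.70, 0.50 and 0.29. Control 3 with GGCT 2 had 0.26 and control 2 with GGCT 3 had 0.20, on the same slide, while the pairs across slides had -0.56 to -0.36, so the slide carries part of this pairing. The replicate number was used as a block in an alternative. Its counts are given beside the total, and beside a list where they differ by over 1.5 times or change which direction has more genes. Genes are not independent replicates in such correlations.

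The procedure was tested on simulated data of 24913 genes, 3 against 3, with 50 changed genes at each size. It recovered 22%, 56%, 88% and 98% of genes with log2 changes of 0.5, 1, 2 and 4, and called 9 of 24683 unchanged genes. The simulated noise was independent between genes and had no slide or replicate effect shared by arrays. Far fewer genes were changed than passed in the data, so these rates need not hold for the data. The first group of alternatives was quantile or median scaling, normexp background correction with an offset of 50, the deposited values, no filter or a filter on all 6 arrays, outlier spots kept, the mean of a gene's probes, every probe on its own, an intensity trend with a robust prior, no moderation, a replicate block, a slide block, the second slide alone and each array left out. Normexp was planned on mean spot signals, which the files do not hold, and used the median spot and median background signals. On the first slide alone there is 1 array per group, so only differences were computed there. A correction for shifts shared by neighbouring genes and 5 further gene lists were added after the data had been seen.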

Results

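GGCT (gamma-glutamylcyclotransferase) releases 5-oxoproline and a free amino acid from gamma-glutamyl dipeptides, a step of glutathione turnover. The series asks how overexpressing it alters gene expression in NIH3T3 cells, a line of mouse embryonic fibroblasts. Cells carrying a GGCT retroviral vector were compared with cells carrying the control vector, with 3 arrays in each group. Each array had 59305 spots besides controls, 56.0% to 60.6% of the probes were well above background, and 0 spots were saturated. The signal at the 75th percentile ranged from 595 to 708 intensity units. Across genes, signals correlated at 0.988 to 0.995 within a group and at 0.970 to 0.978 between groups.

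The gene expression of GGCT-overexpressing cells differed from that of control cells in 6496 genes or accessions. Of 32 genes of the amino acid response driven by the transcription factor ATF4, 23 were lower in GGCT cells, as were 16 of 25 targets of the oxidative stress regulator NRF2, 11 of 22 endoplasmic reticulum chaperones and unfolded protein response genes, 11 of 21 contractile genes and 20 of 38 matrix genes. Of 32 mitotic genes 8 were higher, and of 28 targets of the hypoxia-inducible factor HIF 12 were higher and 5 lower. These lists passed limma's camera with a preset correlation, but 0 of the 37 lists passed with an estimated correlation (smallest adjusted p = 0.245; 7 lists at an unadjusted p under 0.05), fry passed 24, and the HIF call also ended with the replicate block (adjusted p = 0.0541). In 428 genes the signal was well above background on all arrays of one group and on none of the other. The median of their lower bounds was 1.98-fold. At least 8-fold apart were 5 of the 218 higher and 30 of the 210 lower. Among these were Adam22 and Lin28b, detected in GGCT cells, and Tafa5 and Lama4, detected in control cells.

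Of 24935 genes or accessions tested, 6496 (26.1%) passed the threshold, 3408 higher and 3088 lower in GGCT cells. Among those with a gene symbol the balance was the other way, with 2108 higher and 2382 lower. Without the filter on dim probes 4283 passed, 2121 of them higher. With the replicate number as a block, 10864 passed, 5858 higher and 5006 lower, and these held 6447 of the 6496. With the slide as a block 10724 passed, and on the second slide alone, with 2 arrays per group, 6349 passed. The first slide held 1 array per group and allows no test. Among the 6496, 1554 differed at least 2-fold, 648 of them higher and 906 lower. With normexp background correction 632 genes did. The 3 values of one group lay above the 3 of the other in 43.8% of genes, where chance gives 10%. With an array left out, in fits without a slide term, the count was 3663 without control replicate 2, 3504 without control replicate 3 and 3756 without GGCT replicate 3. It was 5317 without control replicate 1, 5300 without GGCT replicate 1 and 4989 without GGCT replicate 2. These fits also have fewer arrays, so they do not show that the count rests on single arrays.

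The Ggct transcript itself, read by 1 mouse probe, was 1.48-fold higher in GGCT cells. Its normalised log2 signal was -0.89 ± 0.085 (SD, n = 3) in control and -0.32 ± 0.24 (SD, n = 3) in GGCT arrays, a difference of 0.57 ± 0.14 (SE; limma adjusted p = 0.031, and 0.0139 with the replicate block). All 3 GGCT values lay above all 3 control values, with differences of 0.38 on the first slide and 0.66 on the second. The call ended without control replicate 1, 2 or 3 or GGCT replicate 3 (adjusted p = 0.075, 0.0725, 0.106 and 0.0824). It also ended with median scaling (0.0611), without the filter on dim probes (0.0788) and without moderation (0.0685), and the range over all alternatives was 0.0139 to 0.106. The species of the construct is not stated, so it is not known whether this probe reads transcript from the vector.

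The 12 genes with the largest fitted rise included a hormone receptor, an RNA-binding protein and members of the Wnt pathway. Their order rests on control values at background for most of them, so that other genes, such as Egln3 at 10.1-fold, rose by more than the lower bounds of some. Agtr2, the type 2 angiotensin II receptor, was at least 56.8-fold higher (adjusted p = 0.000296), with 2 of 3 control arrays well above background. Adam22, a neuronal surface protein of the ADAM family without protease activity, was at least 19.9-fold higher (adjusted p = 7.96e-06). Lin28b, which blocks maturation of let-7 microRNAs, was at least 10.0-fold higher (adjusted p = 4.92e-06). Rnf43, a ubiquitin ligase that removes Wnt receptors, was at least 9.79-fold higher (adjusted p = 0.000262), and the Wnt ligand Wnt10a at least 6.73-fold higher (adjusted p = 1.37e-05). Osbp2, an oxysterol-binding protein detected on all arrays, was 16.7-fold higher (log2 difference 4.06 ± 0.13 SE, adjusted p = 3.37e-05). Rnf207 was 14.9-fold higher by the fit (adjusted p = 0.000286), with 2 of 3 control arrays well above background. The others were the inflammasome protease Casp1 (at least 5.85-fold), the adenylate cyclase Adcy7 (at least 5.78-fold), Samt1c (at least 5.04-fold), the autoimmune regulator Aire (at least 4.30-fold) and the sialic acid lyase Npl (at least 2.97-fold).

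The 12 genes with the largest fitted fall were all detected on the 3 control arrays. Their order too rests on background values, and other genes, such as Mfap5 at 29.2-fold, fell by more than the lower bounds of some. Lama4, a laminin chain of basement membranes, was at least 122-fold lower in GGCT cells by its brightest probe (adjusted p = 1.91e-05; log2 difference -6.12 by its other probe), and the secreted protein Tafa5 at least 118-fold lower (adjusted p = 2.11e-06). Itga11, a collagen-binding integrin chain, was at least 41.4-fold lower (adjusted p = 0.00277), with 1 of 3 GGCT arrays well above background, and Itgbl1 was at least 70.3-fold lower (adjusted p = 1.85e-05), with 2 of 3. The probe named Cthrc1, a gene of collagen matrix, was at least 41.6-fold lower (adjusted p = 3.68e-05), but an earlier version of the array design gives that probe to Alox5. Ctla2a and Ctla2b, near-identical neighbouring genes whose probes were not checked for specificity, were at least 36.1-fold and at least 14.5-fold lower. Kcnj2, an inward-rectifier potassium channel, was at least 32.1-fold lower (adjusted p = 0.000509), and Map2, a microtubule-associated protein, at least 28.2-fold lower by its brightest probe (adjusted p = 6.42e-06; log2 difference -3.22 by its other probe). Jam3, a junctional adhesion molecule, was at least 20.3-fold lower, Pxdc1 at least 18.5-fold and the adrenergic receptor Adra1b at least 14.0-fold.

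**Figure D1:**
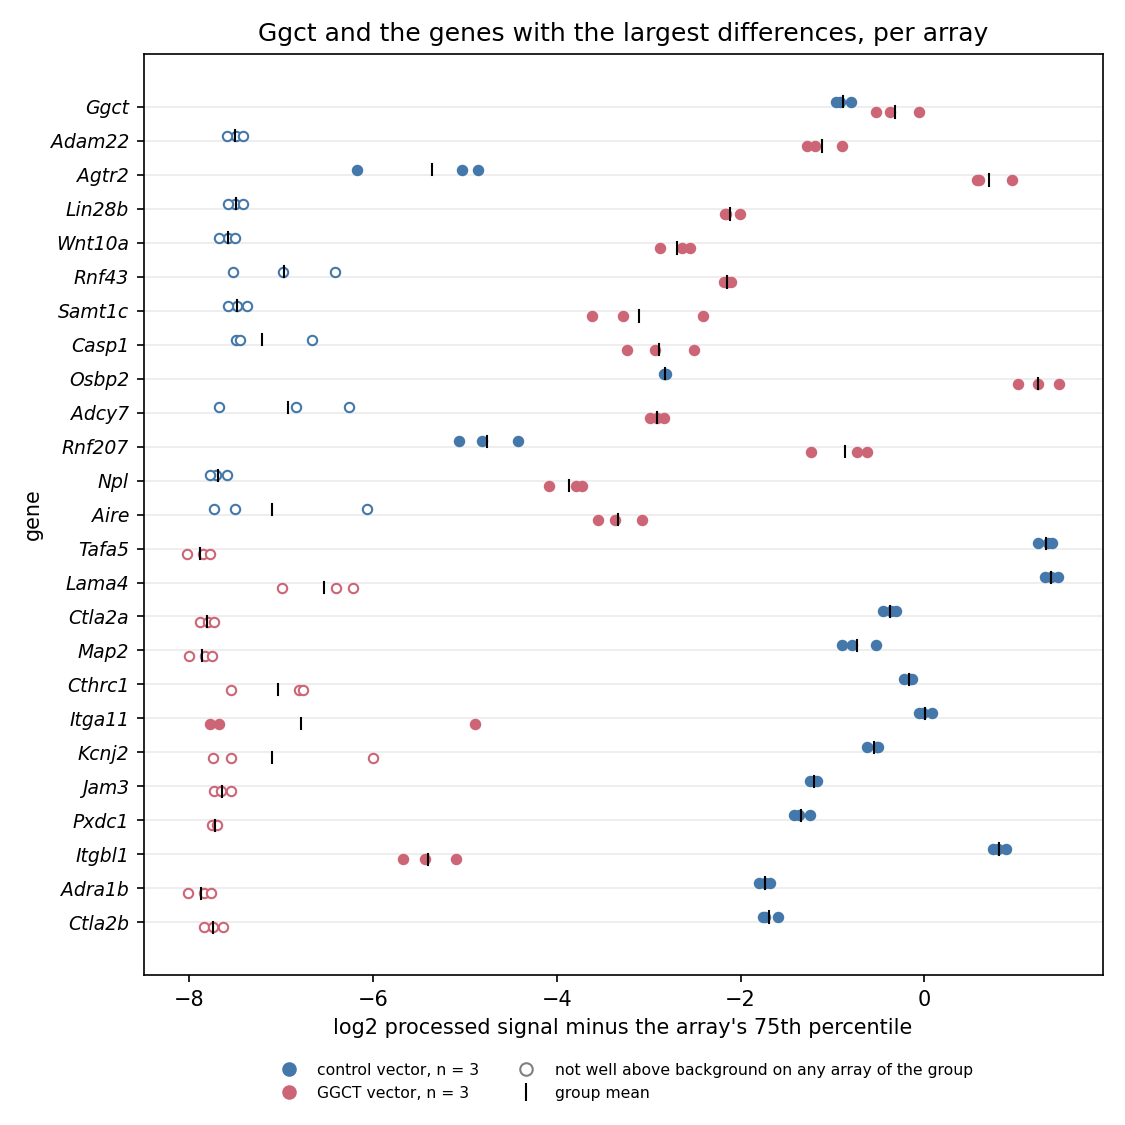
Normalised log2 signal (log2 processed signal minus the 75th percentile of the array, horizontal axis) of Ggct and of the 12 genes with the largest fitted rise and the 12 with the largest fitted fall, with a point per array and a line at each group mean (n = 3 per group). Open points mark groups in which no array was well above background, such as Adam22 in control cells and Tafa5 in GGCT cells; the Ggct groups differ by 0.57.

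The ATF4 amino acid response was the list with the smallest p. Of its 32 measured genes, 23 fell, 2 rose and 7 did not pass, with the same numbers adjusted over the list alone, and the median log2 difference was -0.68. The list passed camera with an adjusted p = 1.18e-07 (adjusted p = 0.245 with an estimated correlation). Chac1, which cleaves glutathione in the cytosol, fell 3.51-fold (log2 difference -1.81 ± 0.11 SE, adjusted p = 0.000335), the stress cytokine Gdf15 fell at least 6.30-fold (adjusted p = 0.000725, 2 of 3 GGCT arrays well above background) and the stress-induced regulator Nupr1 fell 3.36-fold (adjusted p = 0.00103). The lipoprotein receptor Vldlr was at least 7.66-fold lower (adjusted p = 4.92e-06). Atf4 itself, with a log2 difference of -0.71 (adjusted p = 0.00304), and the 2 genes that rose, the hormone Fgf21 and the cationic amino acid transporter Slc7a3 (1.21), were chosen after their values were seen.

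The list of serine synthesis and one-carbon metabolism shares members with that list. Of its 19 measured genes, 6 fell, 0 rose and 13 did not pass, again with 6 and 0 adjusted over the list alone, and camera gave an adjusted p = 0.0441 (adjusted p = 0.51 with an estimated correlation). The call of the list ended with quantile scaling (adjusted p = 0.0642), median scaling (0.0655), the mean of a gene's probes (0.0606), every probe tested on its own (0.0865) and on the second slide alone (0.0952). It also ended when only genes placed on the chromosomes were tested (camera adjusted p = 0.119). Psph, which makes serine from phosphoserine, fell by 0.73 on the log2 scale (adjusted p = 0.00215) and Psat1, the step before it, by 0.40 (adjusted p = 0.0123). The call of Psat1 ended without control replicate 2 (adjusted p = 0.0584), control replicate 3 (0.0623) or GGCT replicate 3 (0.0505).

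Among endoplasmic reticulum chaperones and unfolded protein response genes, 11 of 22 measured fell, 0 rose and 11 did not pass, and 13 fell and 0 rose adjusted over the list alone. Camera gave an adjusted p = 4.62e-06 (adjusted p = 0.245 with an estimated correlation), and the median log2 difference was -0.42. Herpud1, a component of the degradation machinery of the reticulum, fell 3.12-fold (log2 difference -1.64 ± 0.08 SE, adjusted p = 0.000145). Sdf2l1, part of a chaperone complex of the reticulum, fell 2.42-fold, the main luminal chaperone Hspa5 (BiP) 1.60-fold and the transcription factor Xbp1 1.57-fold.

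Of 25 NRF2 target genes measured, 16 fell, 0 rose and 9 did not pass, and 17 fell and 1 rose adjusted over the list alone. Their median log2 difference was -0.52 and camera gave an adjusted p = 4.73e-07 (adjusted p = 0.245 with an estimated correlation). Osgin1 fell 2.81-fold (adjusted p = 0.000334), the epoxide hydrolase Ephx1 2.59-fold (adjusted p = 0.000365) and the quinone reductase Nqo1 1.82-fold (adjusted p = 0.00153).

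Of 29 genes of glutathione use and peroxide removal, 11 fell, 2 rose and 16 did not pass (12 and 2 adjusted over the list alone, 16 and 4 with the replicate block). Camera gave an adjusted p = 0.00203 (adjusted p = 0.245 with an estimated correlation). The extracellular superoxide dismutase Sod3 fell 19.7-fold (log2 difference -4.30 ± 0.17 SE, adjusted p = 8.19e-05), the peroxidase Gpx7 7.82-fold (adjusted p = 0.000135), and the glutathione transferases Gstm2 and Mgst1 5.83-fold and 4.94-fold. The 2 that rose, chosen after their values were seen, were the transferases Gsto1 (log2 difference 1.18) and Gstm5 (0.33).

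In the pathway of GGCT itself, glutathione synthesis and the gamma-glutamyl cycle, 8 of 17 measured genes fell, 1 rose and 8 did not pass, with the same counts adjusted over the list alone. Camera gave an adjusted p = 0.0087 (adjusted p = 0.245 with an estimated correlation). The list shares Chac1, Slc3a2, Slc7a11 and Cth with the ATF4 list and Gclc, Gclm and Slc7a11 with the NRF2 list. It is therefore not separate from them. Besides Chac1, the heavy chain of amino acid transporters Slc3a2 fell 1.62-fold by its brightest probe (adjusted p = 0.00645; log2 difference -0.70, and -0.13 by its other probe) and the cysteine-producing enzyme Cth 2.05-fold (adjusted p = 0.00976). The probe named Oplah, the 5-oxoprolinase that acts on the product of GGCT, fell 2.79-fold (adjusted p = 0.00127), but an earlier version of the array design gives it to Cartpt. Chosen after their values were seen, the catalytic subunit of glutamate-cysteine ligase, Gclc, fell by 0.54 (adjusted p = 0.0161), its modifier subunit Gclm had a difference of -0.25 (adjusted p = 0.136), Gss had 0.13 (adjusted p = 0.43), and the gene that rose was Ggt7 (0.72, adjusted p = 0.0423).

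Collagens and other matrix genes went both ways. Of 38 measured, 20 fell, 8 rose and 10 did not pass (21 and 10 adjusted over the list alone), with a camera adjusted p = 0.00225 (adjusted p = 0.446 with an estimated correlation). Periostin (Postn) fell at least 57.6-fold (adjusted p = 8.9e-05, 2 of 3 GGCT arrays well above background), the microfibril protein Mfap5 29.2-fold (adjusted p = 6.57e-06) and osteoglycin (Ogn) 5.36-fold, and Col12a1 was at least 3.79-fold lower. The proteoglycans decorin (Dcn) and lumican (Lum) rose, 2.52-fold and at least 7.16-fold.

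Of 21 contractile and smooth muscle genes measured, 11 fell, 1 rose and 9 did not pass, with the same counts adjusted over the list alone. Camera gave an adjusted p = 0.000162 (adjusted p = 0.245 with an estimated correlation). Transgelin (Tagln) fell 4.77-fold (adjusted p = 0.000353), the myosin light chain Myl9 4.48-fold (adjusted p = 8.86e-05), the myosin light chain kinase Mylk 2.25-fold by its brightest probe (log2 difference -1.17, and as low as -3.36 over its 3 probes) and the non-muscle myosin Myh9 1.77-fold. The gene that rose was Smtn (0.79), chosen after its value was seen.

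Targets of the transcriptional regulators YAP and TEAD fell in 9 of 22 measured, rose in 1 and did not pass in 12, and the counts adjusted over the list alone were the same. Camera gave an adjusted p = 0.00807 (adjusted p = 0.245 with an estimated correlation). Endothelin 1 (Edn1) was at least 4.46-fold lower (adjusted p = 0.000274), Tgfb2 3.86-fold (adjusted p = 0.00214) and the matricellular protein Ccn2 2.22-fold (adjusted p = 0.0109, and 0.0503 on the second slide alone). The gene that rose was Ankrd1 (0.88), chosen after its value was seen.

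Genes of the TGF-beta response fell in 11 of 26, rose in 5 and did not pass in 10, also adjusted over the list alone, with a camera adjusted p = 0.0388 (adjusted p = 0.446 with an estimated correlation, and 0.119 among only the genes placed on the chromosomes). The mesenchymal transcription factor Snai2 fell 5.25-fold (adjusted p = 0.000247) and the latent TGF-beta binding protein Ltbp2 2.71-fold (adjusted p = 0.000332). The cytokine Il11 rose 3.15-fold (adjusted p = 0.000207) and the activin subunit Inhba 2.72-fold (adjusted p = 0.000977). The others that rose were Tgfb3 (0.80), Tgif1 (0.71) and Skil (0.35), chosen after their values were seen.

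Of 15 Wnt response genes and regulators measured, 6 fell, 2 rose and 7 did not pass, also adjusted over the list alone, with a camera adjusted p = 0.0215 (adjusted p = 0.245 with an estimated correlation, and 0.0679 among only the genes placed on the chromosomes). The secreted Wnt antagonist Sfrp1 was at least 10.5-fold lower (adjusted p = 4.33e-05) and Ccn5 8.03-fold lower (adjusted p = 0.000441). The probe named Ccn4 fell 2.53-fold, but an earlier version of the array design gives it to Sik1. Besides Rnf43, the receptor Fzd2 (0.52), chosen after its value was seen, rose.

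Matrix proteases and their inhibitors fell in 10 of 25, rose in 6 and did not pass in 9, also adjusted over the list alone, with a camera adjusted p = 0.0441 (adjusted p = 0.259 with an estimated correlation, and 0.127 among only the genes placed on the chromosomes). The inhibitor Timp1 fell 3.01-fold (adjusted p = 0.000286), in a run of neighbouring genes with a median log2 difference of -0.62, and the membrane protease Mmp14 fell 2.45-fold (adjusted p = 0.000366). The urokinase gene Plau rose 2.75-fold by its brightest probe (adjusted p = 0.000199), and did not pass with the mean of its probes (log2 difference 1.13, adjusted p = 0.0988).

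Cholesterol synthesis genes fell in 10 of 23, rose in 2 and did not pass in 11, also adjusted over the list alone, with a camera adjusted p = 0.00613 (adjusted p = 0.512 with an estimated correlation). The squalene epoxidase Sqle fell 1.66-fold (adjusted p = 0.00334) and the squalene synthase Fdft1 1.48-fold (adjusted p = 0.00389). The sterol reductase Tm7sf2 rose 1.85-fold (adjusted p = 0.00271), as did Nsdhl (0.33), chosen after its value was seen.

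Interferon-stimulated genes fell in 10 of 23, rose in 3 and did not pass in 10, also adjusted over the list alone, with a camera adjusted p = 0.00873 (adjusted p = 0.446 with an estimated correlation). Trim30a fell 11.3-fold (log2 difference -3.50 ± 0.13 SE, adjusted p = 6.03e-05), Rtp4 2.07-fold and Ifit3 1.97-fold, while the transcription factor Irf7 rose 3.72-fold (adjusted p = 0.00089). Psmb9 (0.86) and Stat2 (0.65), chosen after their values were seen, also rose.

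Lysosome and autophagy genes fell in 10 of 29, rose in 4 and did not pass in 15, also adjusted over the list alone, with a camera adjusted p = 0.0388 (adjusted p = 0.47 with an estimated correlation, and 0.119 among only the genes placed on the chromosomes). The proton pump subunit Atp6v0d1 fell 1.58-fold (adjusted p = 0.00377). The autophagy genes Atg9b and Ulk1 rose 8.08-fold (adjusted p = 0.000915) and 1.66-fold (adjusted p = 0.00189), as did Map1lc3a (0.34) and Neu1 (0.32), chosen after their values were seen.

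The 2 lists that were higher in GGCT cells were mitosis and HIF targets. Of 32 G2/M and mitosis genes, 8 rose, 0 fell and 24 did not pass (7 and 0 adjusted over the list alone, and 14 and 1 with the replicate block). Their median log2 difference was 0.19, and camera gave an adjusted p = 0.00378 (adjusted p = 0.517 with an estimated correlation). The spindle checkpoint kinase Bub1 rose 1.56-fold (adjusted p = 0.004), the phosphatase Cdc25c 1.43-fold (adjusted p = 0.0064) and the kinetochore motor Cenpe 1.39-fold (adjusted p = 0.0118). The call of Cenpe ended without control replicate 2 (adjusted p = 0.0533) or control replicate 3 (0.0531).

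Of 28 HIF target genes, 12 rose, 5 fell and 11 did not pass (13 and 5 adjusted over the list alone), with a camera adjusted p = 0.0484 (adjusted p = 0.583 with an estimated correlation). The call ended with the replicate block (adjusted p = 0.0541), on the second slide alone (0.0601) and among only the genes placed on the chromosomes (0.0513). The HIF prolyl hydroxylase Egln3 rose 10.1-fold (log2 difference 3.34 ± 0.26 SE, adjusted p = 0.000711), Ankrd37 3.64-fold (adjusted p = 0.00322) and the collagen lysyl hydroxylase Plod2 2.26-fold (adjusted p = 0.0037). The 5 that fell, chosen after their values were seen, were Ero1a (-1.13), Bhlhe40 (-0.55), Lox (-0.54), P4ha2 (-0.37) and Bnip3l (-0.36).

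**Figure D2:**
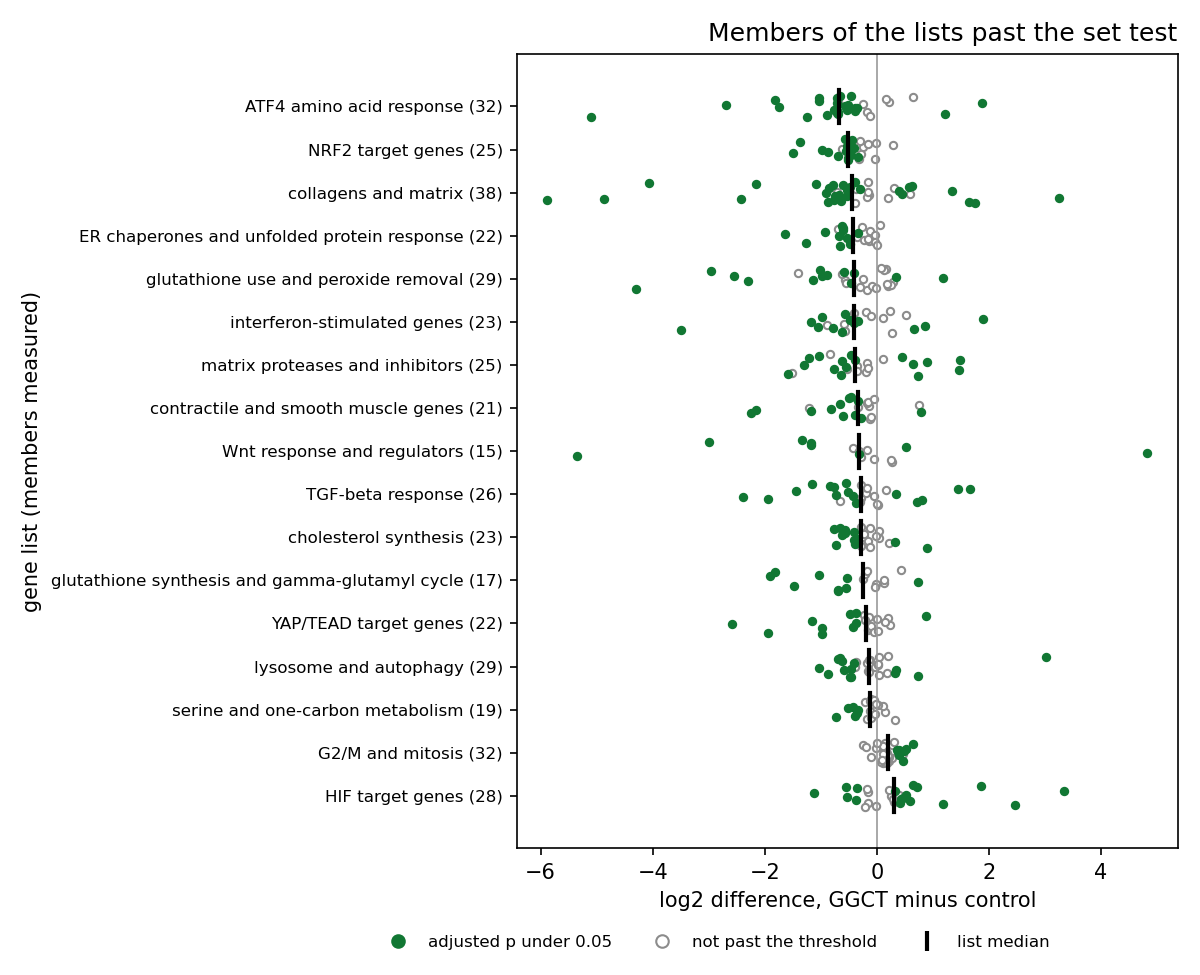
Log2 difference between GGCT and control cells (horizontal axis) of each measured gene in the 17 lists past the set test, with the number of genes measured beside each list. Filled points are genes past the threshold, open points are not, and the bar is the list median, from -0.68 for the ATF4 response to 0.31 for HIF targets.

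All 17 lists had a median of the same sign on both slides, 17 passed with the slide block and 15 on the second slide alone, all but the serine list and HIF targets. The lists had been picked as past the threshold on all 6 arrays, which include these, so this is no independent check. Of the 17, 12 passed under each alternative of the data and the fit that was fixed beforehand and run for lists, which leaves out the fit without moderation and the first slide alone. The other 5 lost it under some. With all arrays kept, besides the serine list, the call of HIF targets ended with median scaling (adjusted p = 0.0548), the deposited values (0.0501), a filter on all 6 arrays (0.0831) and every probe on its own (0.0602). That of matrix proteases ended with median scaling (0.0548), no filter (0.0787), the mean of a gene's probes (0.0599) and every probe on its own (0.277), and that of the TGF-beta response with every probe on its own (0.165). All 5 lost the call with 1 array left out. Without control replicate 2 these were the serine list (adjusted p = 0.0829), HIF targets (0.0737) and the TGF-beta response (0.0669). Without control replicate 3 they were the serine list, HIF targets and matrix proteases (0.0505 each) and the lysosome list (0.0684). Without GGCT replicate 1 they were the serine list (0.122), HIF targets (0.0952), matrix proteases (0.075) and the lysosome list (0.0565), and without GGCT replicate 3 the serine list (0.0553), the TGF-beta response (0.0543) and matrix proteases (0.0504). Camera compares a list with the other genes tested, which include those tested by accession only. Calls were 3408 higher and 3088 lower among all, but 2108 and 2382 with a gene symbol, so a list call can depend on the comparison set. When only the genes placed on the chromosomes were tested, which leaves out the accessions, before any correction, 11 lists passed. The Wnt list, which had held under the settings fixed beforehand, did not (camera adjusted p = 0.0679). Neither did the TGF-beta, lysosome and serine lists (0.119 each), matrix proteases (0.127) and HIF targets (0.0513). Subtracting the median shift of each gene's neighbours ended the calls of cholesterol synthesis (adjusted p = 0.0307 before, 0.0588 after) and YAP/TEAD targets (0.0373 and 0.134). It brought HIF targets (0.0513 and 0.0242) and the TGF-beta response (0.119 and 0.0215) past the threshold, so that 11 passed after it too.

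Several signalling lists held genes with large differences in both directions and did not pass as a group. Adhesion genes and receptor tyrosine kinases had 11 of 31 lower and 7 higher (12 and 10 adjusted over the list alone, 11 and 13 with the replicate block; camera adjusted p = 0.458). Erbb3 fell 17.7-fold (adjusted p = 0.000134), Fgfr1 fell 2.97-fold (adjusted p = 0.000722), the growth factor Igf1 was at least 4.63-fold lower and the laminin-binding integrin chain Itga3 rose 4.30-fold by its brightest probe (adjusted p = 0.000563; log2 difference 2.10, and 0.35 by its other probe). Of 27 secreted inflammatory factors, 5 fell and 7 rose (6 and 10 adjusted over the list alone; camera adjusted p = 0.46). The pentraxin Ptx3 fell 19.9-fold (adjusted p = 0.000247) and the chemokine Cxcl12 was at least 20.9-fold lower, and the cytokines Il33 (2.36) and Il6 (1.54), chosen after their values were seen, rose. ERK-responsive genes had 4 of 25 lower and 8 higher, also adjusted over the list alone (camera adjusted p = 0.458), with the feedback inhibitor Spry1 4.52-fold lower and the transcription factor Etv1 2.49-fold higher. Immediate early genes had 3 of 26 lower and 8 higher, also adjusted over the list alone (camera adjusted p = 0.399), with the nuclear receptor Nr4a1 3.17-fold higher and Egr2 3.11-fold lower.

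Fibroblast identity genes had 8 of 21 lower and 7 higher (8 and 8 adjusted over the list alone and with the replicate block; camera adjusted p = 0.647). The surface protein Ly6a fell 6.48-fold (adjusted p = 0.000118) and the collagen chain Col1a1 2.13-fold (adjusted p = 0.000895). Glycolysis genes had 2 of 21 lower and 5 higher (2 and 6 adjusted over the list alone, 3 and 8 with the replicate block; camera adjusted p = 0.458, and 0.013 with every probe tested on its own). Among the phosphofructokinases, Pfkp fell 4.43-fold (adjusted p = 8.86e-05) and Pfkl rose 1.93-fold (adjusted p = 0.00211). FOXO targets had 4 of 19 lower and 5 higher (4 and 6 adjusted over the list alone, 6 and 6 with the replicate block; camera adjusted p = 0.959), with the death-promoting Bcl2l11 2.24-fold higher by its brightest probe (log2 differences of 0.08 to 1.17 over its 4 probes) and the kinase Pdk4 2.40-fold lower. Targets of p53 and CDK inhibitors had 7 of 24 lower and 3 higher (8 and 3 adjusted over the list alone; camera adjusted p = 0.132), with the death receptor Fas 2.39-fold lower. Heat shock genes and cytosolic chaperones had 7 of 21 lower and 2 higher (8 and 3 adjusted over the list alone; camera adjusted p = 0.0923, and 0.0451 without GGCT replicate 2), with the small heat shock protein Cryab 4.07-fold lower. By fry the lists of adhesion genes, p53 targets and heat shock genes passed (adjusted p = 0.00345, 0.0221 and 0.0303).

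In the machinery of growth and respiration few genes passed. DNA replication and G1/S genes had 4 of 32 lower (Ccnd1, Cdt1, Mcm4 and Mcm3) and 0 higher, none adjusted over the list alone, and 6 and 7 with the replicate block (camera adjusted p = 0.72). Cyclin D1 (Ccnd1) fell 2-fold (adjusted p = 0.0164). Oxidative phosphorylation had 3 of 31 lower (Ndufa1, Sdha and, chosen after its value was seen, Sdhd) and 2 higher (Ndufv2 and Ndufb5), 0 of either adjusted over the list alone, and 4 and 6 with the replicate block (camera adjusted p = 0.911). Cytosolic ribosomal proteins had 1 of 32 lower (Rpl37, 1.81-fold) and 1 higher (Rps2), 1 and 0 adjusted over the list alone, and 3 and 3 with the replicate block (camera adjusted p = 0.466). Ribosome biogenesis and MYC targets had 5 of 30 lower and 1 higher (Polr1b), 0 of either adjusted over the list alone, and 8 and 3 with the replicate block (camera adjusted p = 0.466). Fatty acid synthesis had 2 of 14 lower (Me1 and Acaca) and 1 higher (Fads2), also adjusted over the list alone (camera adjusted p = 0.466). Without control replicate 3, the calls of Ccnd1, Cdt1, Mcm3, Mcm4, Ndufa1, Ndufb5, Ndufv2, Sdha, Rps2, Polr1b, Bop1, Srm, Nop16 and Acaca ended, with adjusted p from 0.0536 for Acaca to 0.123 for Polr1b, and without control replicate 2 that of Fads2 ended too (0.0668). With all arrays kept, median scaling ended the calls of Cdt1, Mcm3, Mcm4, Rps2, Sdha, Ndufb5, Bop1, Srm and Polr1b (adjusted p = 0.0528 to 0.0947). With no filter on dim probes these ended too, as did those of Ndufv2 (0.0539) and Nop16 (0.0752). Rpl37 and Me1 kept theirs with each array left out. Subtracting the median shift of each gene's neighbours ended the calls of Cdt1, Mcm3, Mcm4, Ndufv2, Ndufb5, Rps2 (log2 difference 0.27 before, 0.09 after), Sdha (-0.42 and -0.08), Bop1, Srm, Nop16 and Ndufa1 (-0.37 before; 0.15 after, adjusted p = 0.136).

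Markers of other cell types did not pass as lists with all 6 arrays and the filter used here. The macrophage list passed on the second slide alone (adjusted p = 0.0357) and without control replicate 1 (0.0355). The cartilage and bone list passed with no filter (0.0487), a filter on all 6 arrays (0.0189) and without GGCT replicate 2 (0.0374). By fry, which does not compare a list with other genes, both passed, as did epithelial and skeletal muscle markers. Cartilage and bone markers had 3 of 10 measured lower (Spp1, Col10a1 and Col2a1) and 1 higher (Ihh), or 4 and 1 adjusted over the list alone and 6 and 1 with the replicate block (camera adjusted p = 0.0734). Macrophage markers had 2 of 7 lower (Aif1, 3.61-fold, and Tyrobp, at least 2.05-fold) and 0 higher, also adjusted over the list alone (camera adjusted p = 0.0877). Adipocyte markers had 2 of 7 lower (Lpl and Plin4) and 1 higher (Dgat2, 2.42-fold), or 3 and 1 adjusted over the list alone (camera adjusted p = 0.336). Skeletal muscle markers had 3 of 8 lower (Acta1, 10.1-fold, Tnnc1 and Actc1) and 2 higher (Tnnt1 and, chosen after its value was seen, Tnnt3), also adjusted over the list alone (camera adjusted p = 0.466). Of 5 epithelial markers 1 was lower (Krt14, 3.16-fold) and 0 higher, and of 5 endothelial markers 1 was lower (Egfl7, at least 21.1-fold) and 1 higher (Cdh5, at least 2.89-fold), both also adjusted over the list alone (camera adjusted p = 0.573 and 0.943). Without control replicate 3 the calls of Col2a1, Actc1, Tnnc1, Ihh and Plin4 ended (adjusted p = 0.086, 0.064, 0.0512, 0.0589 and 0.118), and without GGCT replicate 3 that of Tnnt1 (0.0516). In 9 lists, all without a camera call, the median, the mean and the direction of the test differed in sign.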

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

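The correction for neighbouring genes and the replicate block with an estimated correlation were chosen after the data had been seen. Signal over background limits what can be said of dim genes, since 31 of the 158 named genes were well above background on no array of 1 group. The count of 6496 genes became 4283 (2121 higher) without the filter on dim probes, where more genes were tested, 10864 (5858 higher, 5006 lower) with the replicate block and 10724 (5774 and 4950) with the slide block. Among the 14525 placed genes alone, 5307 passed before the median shift of each gene's neighbours was subtracted and 4202 (1983 higher) after it. Genes at least 2-fold apart went from 1113 to 1035. Before it 11 lists passed and after it 11, with 9 passing both times. Normexp background correction left 632 genes at least 2-fold apart, against 1554. Its offset of 50 is added to each signal and exceeds the median processed signal of every array (36.1 to 44.7). This setting therefore lowers the folds of dim genes by design. How much of the fall in the count it accounts for was not tested. All other settings fixed beforehand that kept the 6 arrays, and the second slide alone, gave 5555 to 7194 genes, and testing every probe gave 8425 of 32419 probes. With an array left out, the total ranged from 3504 to 5317, genes higher from 1719 to 2928, genes lower from 1785 to 2771, genes at least 2-fold apart from 1419 to 1616, lists from 13 to 19 and the log2 difference of Ggct from 0.44 to 0.67. The total moved by over 1.5 times without control replicate 2 (3663), control replicate 3 (3504) and GGCT replicate 3 (3756). Genes higher were 52.5% of the calls, and 47.2% to 55.1% over the alternatives. At least 2-fold apart were 648 higher and 906 lower, and with a gene symbol 2108 and 2382, so the balance differs between parts of the calls. The Ggct difference was 0.57 with median scaling (adjusted p = 0.0611), with no filter (0.0788) and without moderation (0.0685), none past the threshold; the cause was not tested. Camera passed 0 lists with an estimated correlation, and 0 with it and the replicate block. Of the 158 named genes, 136 kept the call under each setting fixed beforehand that kept all arrays or the second slide and tested them (39 were not tested with the filter on all 6 arrays), 128 with each array left out, and 0 reversed. The named genes had been chosen as past the threshold on these same arrays. A reversal could therefore hardly occur, and its absence is no support. After the neighbour correction 13 lost it, among them Ndufa1, which went from -0.37 to 0.15 in a run of genes with a median of -0.52.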

Other observations

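The gene lists of these opening paragraphs and the tests of gene order, near-identical neighbours, other cell types and, in its second form, founder cells at each experiment were chosen after results had been seen. Hox genes, the position regulators of the embryo, had more genes higher than lower in GGCT cells. Of 22 measured, 11 rose, 2 fell and 9 did not pass, with a median log2 difference of 0.51 and a camera adjusted p = 0.0106 over 6 lists (adjusted p = 0.719 with an estimated correlation). Hoxd3 (1.05), Hoxb4 (0.93) and Hoxa5 (0.69) rose, while Hoxb9 fell at least 10.2-fold and Hoxc9 by 0.68. Hox genes lie in clusters, so their differences are not independent.

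Imprinted genes, which are expressed from one parental copy, had 9 of 27 higher and 4 lower (camera adjusted p = 0.49). The growth factor Igf2 (1.72), the zinc finger genes Plagl1 (1.60) and Peg3 (1.54) and the neighbour of Peg3, Usp29 (0.99), rose. The non-coding RNA Meg3 was at least 6.55-fold lower and Mirg, from the same imprinted region, fell by 1.72. Axon guidance genes had 9 of 42 higher and 7 lower (camera adjusted p = 0.698), with the ephrin receptor Epha4 at least 7.07-fold lower and the semaphorin Sema7a higher by 2.24. Receptors for vasoactive hormones had 5 of 25 higher and 5 lower (camera adjusted p = 0.624), with the endothelin receptor Ednra at least 15.2-fold lower and the melanocortin receptor Mc2r at least 2.21-fold higher. The imprinted and vasoactive lists were drawn up partly because of genes already seen.

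Among the 10 splits of the 6 arrays into groups of 3, 1, the real split, gave as many as 6496 genes past the threshold, and the highest of the others gave 1. The splits are too few for a share under 0.05. Of the other 9 splits, 3 also part all same-numbered pairs, while 6 keep a pair together, among them the split that gave 1 gene.

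Genes that lie near each other on a chromosome shifted together. The rank correlation of the log2 differences of genes 50 places apart was 0.139, above all of 1000 random gene orders (largest 0.0284, permutation p = 0.001, the smallest they can give). Its reach also argues against probes shared by near-identical neighbours, and the correlation of run medians between the slides (0.968) and its small size within groups (0.0675 of that between groups) argue against an artefact of a slide or of gene position. A candidate explanation is a difference in chromosome copy number between the cell populations, since the chromosome medians of 2210 non-coding probes followed those of the placed genes over 20 chromosomes (r = 0.879, permutation p = 1e-05, the smallest possible; rho = 0.859, permutation p = 2e-05; r = 0.843 without the 2 farthest), but shared regulation along a chromosome was not tested and DNA was not measured. Chromosome medians ranged from -0.27 (chromosome 13) to 0.22 (chromosome 10). Medians of runs of up to 51 neighbouring genes ranged from -0.59 to 0.33, and chromosome medians do not show such segments. After subtracting each gene's local shift, 67.3% of the calls among placed genes remained. Of the 5307 calls before it, 1113 were at least 2-fold apart, which is more than these run medians, so part was bound to remain. The subtraction also leaves any further effect of a difference between the populations in place. It shows only that the local shift itself does not account for most calls.

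Of the genes tested, 218 were well above background on all GGCT arrays and no control array, and 210 the reverse. Cells of 1 of the 6 other types listed stay open. The largest share of such a list past the threshold in one direction was 60% with the replicate block (cartilage and bone, 6 of 10 lower). Without the block the largest share was 37.5% (skeletal muscle), and cartilage and bone had 30%. The cartilage and bone list did not pass camera with the block (adjusted p = 0.0817). A separate change of founder cells at each experiment was first tested on these 428 genes, of which 65.0% were at least 2-fold apart in all 3 same-numbered pairs. This lay between the bounds set beforehand and decided nothing. Those genes had been chosen on all 3 pairs, so a second test with other bounds was added. In it, 255 genes were detected in 1 of the replicate 1 arrays and were at least 4-fold apart there. Of these, 84.3% were at least 2-fold apart the same way in both other same-numbered pairs and 0 the opposite way. The filter had asked for detection on at least 3 of the 6 arrays. These genes were therefore not chosen on replicate 1 alone, and genes detected only there were left out beforehand. This can raise the share, so the second test does not decide either. A change of founder cells when the stable lines were made, before the experiments, could give the same pattern and was not tested, as the labels do not say how many infections were done. A direct or indirect effect of GGCT stays among the open explanations.

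Lin28b, which blocks let-7 microRNAs, was above background in GGCT cells only, so let-7 targets were tested for a rise. Without Hmga2 and Igf1r, whose values had been seen, the 32 measured targets had a median log2 difference of 0.022, with 5 higher and 3 lower (camera adjusted p = 0.698). With members going both ways, this decides nothing about let-7 activity.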
